A study of Homo sapiens with 10 samples.

How the data were processed

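RNA was measured in HEK-293 cells on HuGene-1_0-st arrays, in 5 groups of 2 biological replicates (10 arrays): cells given a scramble siRNA, each of 2 siRNAs against LINC00324, and each of 2 siRNAs against LOC400043, at 10 nM with RNAiMax. Per the labels, total RNA was extracted with Trizol and labelled with biotin. Per the labels, RMA and limma were used, without versions; RMA corrects background, normalizes by quantiles and summarises probes. The genome build behind the coordinates is not given in the sources used here.

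The authors deposited 2 tables of log2 values, 1 for each silenced RNA, with 18480 features in 2 scramble and 4 silenced arrays each, and with a log2 ratio of silenced to scramble per gene. The authors also deposited an unadjusted p-value per gene in each table, per the file headers. The deposited log2 ratio was checked to be the mean of the 4 silenced arrays minus the mean of the 2 scramble arrays, with a largest difference of 0.0005. The deposited p-values rank genes as a fit with the silenced arrays as 1 group does (Spearman 0.9996 and 0.9999 across genes). A p under 0.05 was given to 1468 genes for LINC00324 and 3229 for LOC400043 in the authors' deposited tables, and 12 and 385 of these passed after Benjamini-Hochberg adjustment in the present work.

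The scramble arrays have different values in both tables: their median log2 level was 0.11 higher in the LINC00324 table, and the SD of the difference over genes was 0.14, so that the tables were normalized separately. A deposited value table of 33297 features in log2 units holds the scramble and LINC00324 arrays of 1 normalization beside the LOC400043 arrays of the other, and LOC400043 arrays were therefore not set against scramble in it. It was used only for the 10355 features that have no name in either table and for an alternative over 29086 features; 4211 features numbered below the lowest named transcript cluster were left out as controls.

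Symbols were brought to current ones through the accessions of each feature (17289 features of the LINC00324 table and 17294 of the LOC400043 table), by synonym (339 and 338) or kept. Of 25 symbols that had become dates in each table, 24 were restored through an accession or left. Where a gene had several features, that with the highest mean was kept, which left 18444 and 18442 genes. The feature kept lay on another chromosome than the gene of its symbol in the reference for 113 of 18030 and 112 of 18027 genes that could be compared, and such features stayed under the name given in the deposited tables. No filter on dim genes was applied.

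Each table was fitted on its own in limma 3.58.1 (R 4.3.3, statmod 1.5.0) with 1 mean per siRNA group, and contrasts were tested with moderated statistics and Benjamini-Hochberg adjustment over all genes, at a threshold of 0.05. Silencing of an RNA was the mean of its siRNAs against scramble; each siRNA against scramble and siRNA 1 against siRNA 2 were tested in the same fit. The plan had been a single fit of all 10 arrays, which the separate normalization ruled out. Joined through the scramble arrays, all 10 arrays gave 849 genes for LINC00324 where the fit within the table gave 88, and 3135 where it gave 3240 for LOC400043. LINC00324 silencing was compared with LOC400043 silencing on values relative to the scramble mean of each table, over 18191 genes and 8 arrays. LOC400043 was not named in either table and its level was not analysed here.

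Gene lists (31, written beforehand) with at least 3 measured members were tested with limma camera at a preset correlation of 0.01 between genes, with Benjamini-Hochberg adjustment over the lists, and again with an estimated correlation and with fry. The correlation of effects across genes was set against 100 simulations of unchanged groups that share the scramble arrays (seed 1). Of simulated data with 200 changed genes in 10 runs, the fit recovered 72% of changes of 0.5 on the log2 scale for LINC00324. It recovered 99.4% of changes of 1 there, and 94.2% and 100% for LOC400043, with 5.4% and 6.5% false calls. The simulated genes were independent, took the moderated SDs as true and changed alike with both siRNAs, so real recovery may be lower.

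The genes named are the silenced RNAs and, for each silencing against scramble, the 10 highest and 10 lowest log2 changes past the threshold with the same sign for both siRNAs and all 4 silenced arrays on the same side of both scramble arrays. For single siRNAs, for siRNA 1 against siRNA 2 and for LINC00324 against LOC400043 they are the 5 largest in each direction past the threshold, and from each list up to 4 members with the smallest p. Other genes named beside a list or a count, such as JUN, BIRC5 and IFI27, were chosen after their values were seen where they fall outside this rule. The rule, the lists, the contrasts and most alternatives were chosen before the data were examined. The fit within each table was not, and replaced the planned fit of all 10 arrays.

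The alternatives were a replicate block, a filter on dim genes, quantile normalization, median centring, a trended and robust variance, array weights, the mean of a gene's features, all features of the value table, 1 group per silenced RNA, a test against a fold of 1.2 (treat), a call for each siRNA alone, scramble arrays not shared between siRNAs, and leaving out each array. The number of arrays, 2 per group, limits the precision.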

Results

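Gene expression was profiled in HEK-293 cells, a human embryonic kidney line that takes up siRNA readily, on HuGene-1_0-st arrays, which read each gene with probes spread along its exons. The series title places the arrays in a search for long noncoding and circular RNAs that act as microRNA sponges. Cells were transfected with 10 nM of a scramble siRNA, of either of 2 siRNAs against LINC00324, or of either of 2 siRNAs against LOC400043, both of them long noncoding RNAs. This gave 5 groups of 2 biological replicates, 10 arrays in all. The deposited values came in 2 tables, 1 for each silenced RNA, each with its 4 silenced arrays and the same 2 scramble arrays. The median log2 level of an array lay between 7.64 and 7.73 in the LINC00324 table and between 7.53 and 7.62 in the LOC400043 table. The replicates of a group differed from gene to gene with an SD of 0.13 to 0.24 on the log2 scale, and the number of arrays limits the precision of every comparison.

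The first question was whether the silenced RNAs were lower in the arrays labelled with their siRNAs. LINC00324 (transcript cluster 8012416, listed as C17orf44) lies on the minus strand of chromosome 17 from 8123948 to 8127361, in a genome build not given in the sources used here. Its log2 level was 5.80 ± 0.01 (SD, n = 2) with scramble, 5.20 ± 0.24 (SD, n = 2) with siRNA 1 and 5.42 ± 0.25 (SD, n = 2) with siRNA 2, and all 4 silenced arrays lay below both scramble arrays. The mean difference was -0.49 (SE 0.13), or 0.714 of the scramble level, with an adjusted p of 0.185 in limma after Benjamini-Hochberg adjustment. It was thus not past the threshold of 0.05, and neither was the difference of siRNA 1 (-0.60, adjusted p = 0.184) or siRNA 2 (-0.38, adjusted p = 0.308). The authors' deposited table gives this difference an unadjusted p of 0.0146. Their p for LINC00324 RNA with LOC400043 silenced, where LINC00324 was not targeted, is 0.0188. In the cells with LOC400043 silenced, LINC00324 differed from scramble by -0.23 (SE 0.07, adjusted p = 0.057 in limma), and the gap between both silencings was -0.25 (SE 0.10, adjusted p = 0.117). The RNA was dim, below the lower quartile of its arrays, which ranged from 5.97 to 6.21. The level of LOC400043, known today as LINC02381, was not analysed here, so its silencing was not checked.

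**Figure D1:**
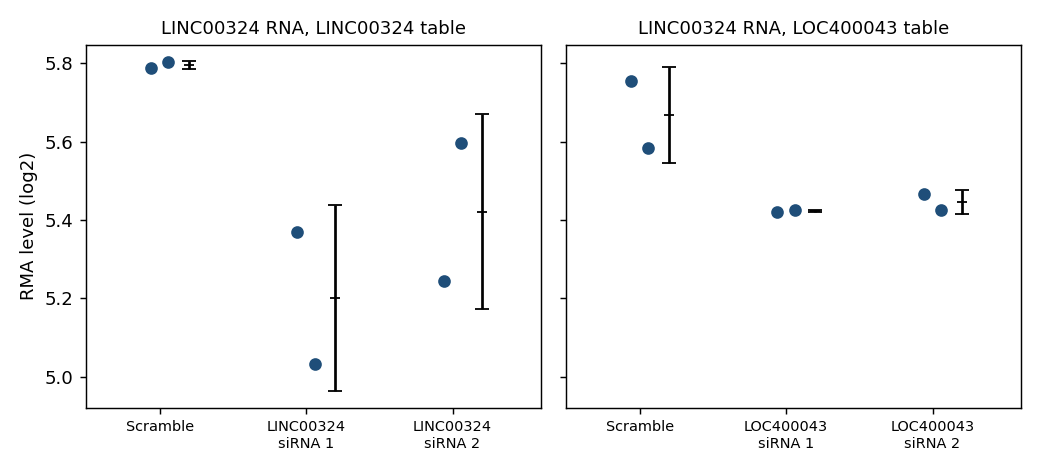
Log2 RMA level of LINC00324 in each array (points) of the LINC00324 table (left) and of the LOC400043 table (right), by siRNA group, with the mean and SD of the 2 replicates beside the points. In the LINC00324 table the scramble arrays sit at 5.79 and 5.80 and the 4 silenced arrays between 5.03 and 5.60.

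The comparison of LINC00324 silencing with scramble asked which genes change when this RNA is targeted, and several of the genes that fell are p53 targets. The largest fall was that of OSTN, which encodes the secreted peptide osteocrin, by 2.03 (SE 0.15) on the log2 scale, to 0.245 of scramble. ACTA2, smooth muscle actin, fell by 1.56 (SE 0.08), and EDA2R, a receptor of the tumour necrosis factor family, fell to 0.435 of scramble. RNF167, an E3 ubiquitin ligase of endosomes, rose by 1.22 (SE 0.07), to 2.34 times scramble, and the carbonic anhydrase gene CA2 rose to 2.30 times scramble. SHMT2, which makes glycine from serine in mitochondria, rose by 1.19 (SE 0.06). The other named genes that rose were the complex I subunit NDUFB5, TMEM9B, the late endosome GTPase RAB9A, the transcription factor ETV1, the kinase HIPK3, the ESCRT ATPase VPS4A and PHGDH, the enzyme that opens serine synthesis, by 0.98 to 1.15. The other named genes that fell were QPCT, SPATA18, the phosphatase INPP5D, ZMAT3, BTG2, the death receptor FAS and PTPRJ, with log2 changes of -1.01 to -0.87. In limma, 88 of 18444 genes passed an adjusted p of 0.05, with 36 higher and 52 lower, and 13 of them changed at least 2-fold; the named genes had adjusted p of 0.00448 to 0.0437. The excess of lower genes depends on the scaling, since the split was 35 higher and 34 lower with each array centred on its median, 156 and 152 after quantile normalization, and 14 and 9 over all features of the value table. The count fell to 0 without either scramble array or either siRNA 2 array (limma, 1382 to 2035 genes at an unadjusted p under 0.05). It was 12 in a test against a fold of 1.2 and 1060 with a trended, robust variance, so these calls rest on few arrays and on the model of the spread.

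Of 24 measured p53 targets, genes that the tumour suppressor p53 switches on, 8 fell with LINC00324 silenced, none rose, and 20 fell when adjusted over the list alone. SPATA18 fell by 1.01 (SE 0.09), BTG2 by 0.90 (SE 0.08), the DNA repair gene DDB2 by 0.82 (SE 0.09) and TP53I3 by 0.71 (SE 0.08), and ZMAT3, FAS, SESN1 and FDXR fell as well. The median of the list was -0.46, and -0.55 and -0.39 with siRNA 1 and siRNA 2 (limma camera, adjusted p = 1.25e-19, and adjusted p = 0.443 with an estimated correlation). Among 29 genes of the amino acid response driven by ATF4, 3 rose and 12 rose when adjusted over the list alone, with a median of 0.16. These were SHMT2, PHGDH at 0.98 (SE 0.06) and the cystine transporter SLC7A11 at 0.97 (SE 0.07), while PSAT1 measured 0.50 (SE 0.07, adjusted p = 0.0583). The list passed in camera (adjusted p = 2.59e-10, and adjusted p = 0.847 with an estimated correlation). The apoptosis regulators held 1 gene that fell among 22, APAF1 by 0.72 (SE 0.09), with 2 adjusted over the list alone, and were not shifted as a list (camera adjusted p = 0.755).

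Smaller shifts were found in 4 further lists with LINC00324 silenced. The 20 immediate early genes, which answer growth signals within minutes, had a median of -0.15, with FOS at -0.40 (SE 0.10) and FOSB at -0.45 (SE 0.11). None of them passed over all genes and 3 did when adjusted over the list alone (camera adjusted p = 0.000272, and adjusted p = 0.594 with an estimated correlation). The 28 genes of the G2 and M phases had a median of 0.09, with CDC20 at 0.32 (SE 0.07) and BIRC5 at 0.29 (SE 0.06), and 2 passed adjusted over the list alone (camera adjusted p = 0.00481). The 17 genes of the unfolded protein response had a median of -0.09, with HYOU1 at -0.41 (SE 0.07), and 2 passed adjusted over the list alone (camera adjusted p = 0.00861). Of 466 zinc finger genes named ZNF, 1 fell, ZNF704 by 0.84 (SE 0.09), over all genes and adjusted over the list alone, around a median of -0.06 (camera adjusted p = 0.0139). With an estimated correlation the adjusted p of each of these 3 lists was 0.847, and limma's fry passed 3 lists, the p53 targets (adjusted p = 0.012), the ATF4 response (adjusted p = 0.043) and 4 reported miR-615-5p targets (adjusted p = 0.012). Among those 4, SHMT2 alone rose, over all genes and adjusted over the list alone, and camera gave the list an adjusted p of 0.227.

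On the mean of both siRNAs, lists that bear on small RNAs, on the interferon response and on the neighbourhood of LINC00324 were not shifted in camera. Among 9 measured neighbours on 17p13.1 no gene changed, over all genes or adjusted over the list alone, and TMEM107 had the smallest p at -0.16 (SE 0.09, adjusted p = 0.476 in limma). The 16 genes of the small RNA pathway gave 0 changed genes by either adjustment (limma, camera adjusted p = 0.134), with DICER1 at -0.23 (SE 0.06). With siRNA 1 alone, the small RNA pathway (camera adjusted p = 0.0226), the box C/D snoRNAs (0.000135) and the box H/ACA snoRNAs (1.5e-05) were lower, and with siRNA 2 alone they were not shifted (0.822, 0.334 and 0.0614). With an estimated correlation the adjusted p of each of these lists with siRNA 1 was 0.831. In the direct test of siRNA 1 minus siRNA 2 the small RNA pathway did not pass in camera (adjusted p = 0.109), the snoRNA lists did (1.84e-05 and 1.81e-09), and with an estimated correlation none of them did (0.845 for each). The 16 reported miR-96-5p targets gave 0 as well (camera adjusted p = 0.454). The 36 interferon response genes, a common sign of a reaction to transfected RNA, had a median of 0.05 and 0 changed members by either adjustment (camera adjusted p = 0.544). The scramble cells were transfected too, so a reaction common to all cells would not show in this comparison. Of 187 microRNA genes 0 passed by either adjustment (camera adjusted p = 0.117), and MIR21 measured -0.45 (SE 0.06, adjusted p = 0.0538).

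Each siRNA against LINC00324 changed genes that the other did not. With siRNA 1, ETV1 rose by 1.53 (SE 0.15), PAPSS2 by 1.24 (SE 0.13) and the integrin gene ITGA8 by 1.22 (SE 0.14), and the zinc finger gene ZPR1 fell by 1.38 (SE 0.10). With siRNA 2, the steroid dehydrogenase gene HSD17B6 rose by 1.35 (SE 0.14), and the histone demethylase gene KDM7A fell by 1.51 (SE 0.17) and PAFAH1B2 by 1.43 (SE 0.09). Tested directly, siRNA 1 minus siRNA 2, the largest gaps were 1.64 (SE 0.11) for LOC388022 and -2.05 (SE 0.12) for the pseudogene ADCY10P1, each of which changed in opposite directions with both siRNAs. ANXA3, PRKCH, PAFAH1B2 and EDIL3 were higher with siRNA 1 by 1.23 to 1.34, and MRPL51, HDHD5, ZPR1 and a feature named TPI1 differed by -1.30 to -1.24. The TPI1 feature lies on chromosome 1 from 77165440 to 77166690, away from the coding gene on chromosome 12 in the reference, and its value is not that of the coding gene. In limma, siRNA 1 changed 92 genes (40 higher, 52 lower), siRNA 2 changed 337 (91 higher, 246 lower), and 571 genes differed between them, 424 higher and 147 lower with siRNA 1. With each array centred on its median, siRNA 2 gave 135 higher and 183 lower genes and the direct comparison gave 298 higher and 225 lower. After quantile normalization the direct comparison gave 725 higher and 427 lower, and siRNA 1 gave 179 higher and 161 lower. The excess of lower genes with siRNA 1 thus depends on the scaling. The calls of each siRNA and between them rest on few arrays, as those on the mean do.

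Both siRNAs against LINC00324 changed 33 genes in the same direction, 17 higher and 16 lower, where independent lists would share 0.197 and 0.694, and 2 genes in opposite directions. Of the 88 genes called on the mean, RNF167, CA2 and SHMT2 among them, 87 had the same sign with both siRNAs, and 25, ETV1 and SPATA18 among them, also differed between the siRNAs. Over 18444 genes, which are not independent replicates, the effects of both siRNAs correlated at 0.417 with a covariance of 0.0158. Unchanged groups set against the same scramble arrays gave 0.499 and 0.00699, so that the covariance exceeded the simulated value by 0.0088. The shared genes were not counted with the scramble arrays split between the siRNAs, and part of their excess may come from these arrays. With a different scramble array for each siRNA the correlation was 0.196 or 0.116. Leaving out 1 array gave correlations from 0.253 to 0.592.

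**Figure D2:**
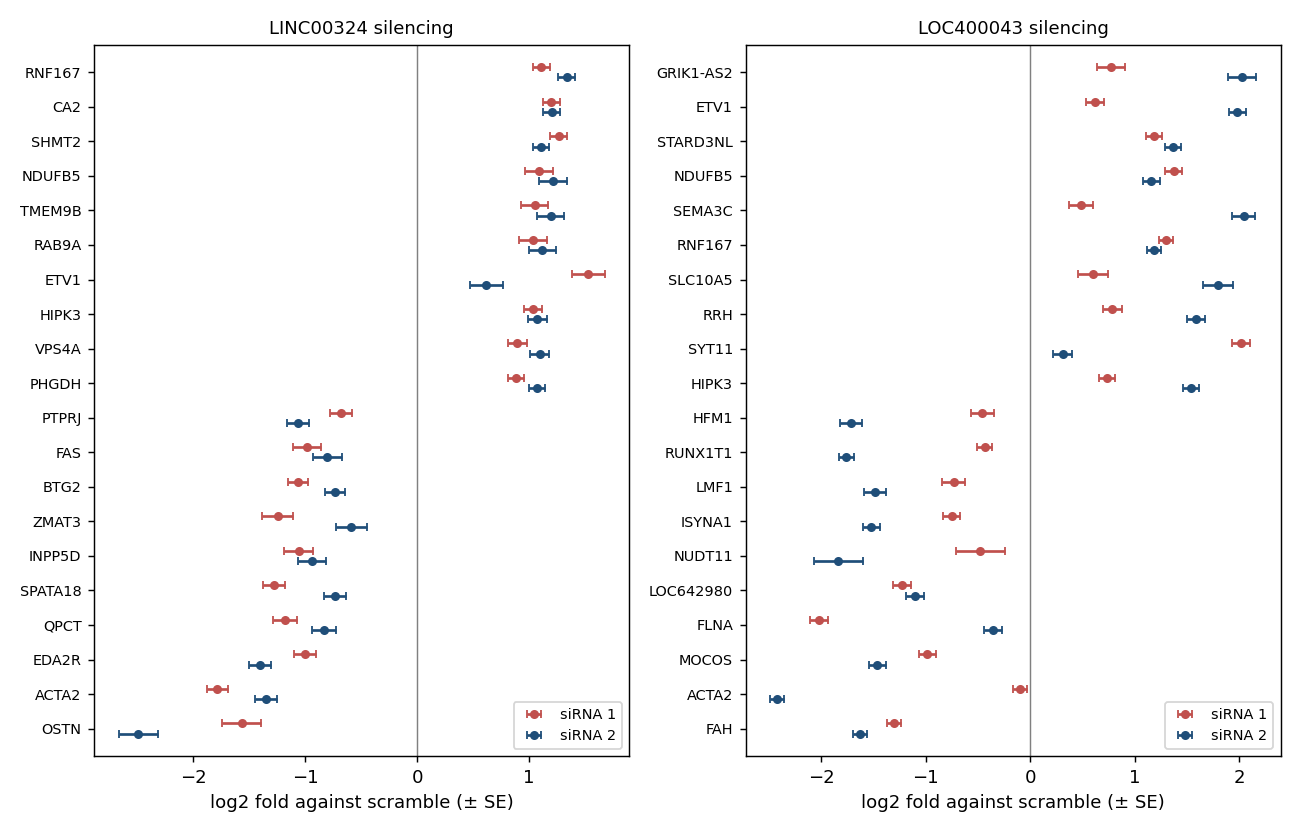
Log2 change against scramble with siRNA 1 (red) and siRNA 2 (blue) for the 20 genes named for LINC00324 silencing (left) and the 20 named for LOC400043 silencing (right); bars are the standard error from limma. RNF167 lies between 1.11 and 1.34 with all 4 siRNAs, while ACTA2 is at -0.10 with LOC400043 siRNA 1 and at -2.42 with siRNA 2.

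More genes were called with LOC400043 silenced than with LINC00324 silenced, and genes of cholesterol synthesis were among those that fell. The spread was unequal, since the SD of the difference between replicates was 0.24 for LINC00324 siRNA 1 and 0.13 for LOC400043 siRNA 1. The calls weigh the spread between replicates of an siRNA and not that between siRNAs. FAH, the last enzyme of tyrosine breakdown, fell by 1.47 (SE 0.06), to 0.362 of scramble, and fell with siRNA 1 (-1.30) and siRNA 2 (-1.63) alike in sign. MOCOS, which activates molybdenum enzymes, fell by 1.22 (SE 0.07), FLNA, the actin crosslinker filamin A, by 1.19 (SE 0.07), and ISYNA1, which makes inositol phosphate, by 1.14 (SE 0.07). ACTA2 fell by 1.26 (SE 0.06) on the mean, and LOC642980, NUDT11, the lipase maturation factor LMF1, RUNX1T1 and HFM1 had changes of -1.16 to -1.09. The antisense RNA GRIK1-AS2, listed as NCRNA00258, rose by 1.40 (SE 0.12) and the transcription factor ETV1 by 1.30 (SE 0.07). STARD3NL, an endosomal membrane protein gene, rose by 1.28 (SE 0.07), NDUFB5 by 1.27 (SE 0.07) and RNF167 by 1.24 (SE 0.06), and SEMA3C, SLC10A5, RRH, SYT11 and HIPK3 rose by 1.14 to 1.27. In limma, 3240 of 18442 genes passed, 1123 higher and 2117 lower, of which 32 changed at least 2-fold, and the 20 named genes had adjusted p of 0.000981 to 0.0111. With each array centred on its median the split was 1587 higher and 1620 lower, so the excess of lower genes depends on the scaling. The count was 599 with the siRNAs pooled as 1 group and 357 in a test against a fold of 1.2, and between 1462 and 1846 without any 1 of the 4 silenced arrays.

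Of 24 genes of cholesterol synthesis and uptake, 11 fell with LOC400043 silenced, 0 rose, and 13 fell when adjusted over the list alone. INSIG1, which holds back the sterol-regulated transcription factors, fell by 0.72 (SE 0.06), lanosterol synthase LSS by 0.64 (SE 0.06), TM7SF2 by 0.54 (SE 0.06) and FDPS by 0.46 (SE 0.06). The regulator SREBF2 fell too, and the median was -0.27 with siRNA 1 and -0.21 with siRNA 2 (camera adjusted p = 9.77e-05, and adjusted p = 0.796 with an estimated correlation). Of the 24 p53 targets 12 fell, and 13 fell when adjusted over the list alone, with SPATA18 at -0.95 (SE 0.10), FAS at -0.74 (SE 0.09) and TP53I3 at -0.57 (SE 0.07). Their median was 0.07 with siRNA 1 and -0.49 with siRNA 2 (camera adjusted p = 1.54e-05 on the mean, and adjusted p = 0.343 with an estimated correlation). Of 24 hypoxia and glycolysis genes 7 fell and 1, ENO2, rose, with BHLHE40 at -0.62 (SE 0.07) and HK2 at -0.49 (SE 0.08), and 9 fell and 1 rose adjusted over the list alone (camera adjusted p = 0.0248). Of 75 ribosomal protein genes 7 rose and 2, RPL10 and RPL22L1, fell, with RPL27A at 0.65 (SE 0.07), and 6 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.0248). Neither of these last lists passed with an estimated correlation (adjusted p = 0.796 for each).

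**Figure D3:**
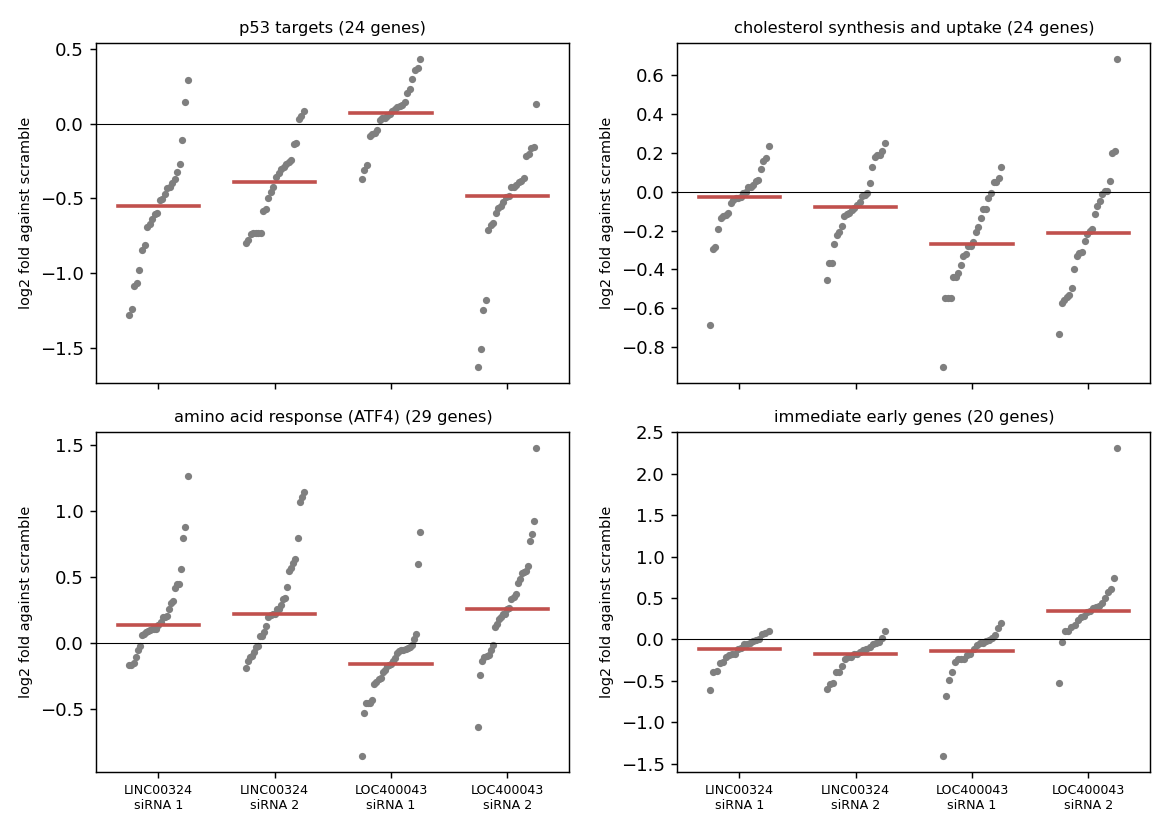
Log2 change against scramble of each measured member (points) of 4 gene lists with each of the 4 siRNAs; red lines are medians and the points of a group are sorted. The p53 targets have medians of -0.55, -0.39, 0.07 and -0.49 from left to right, and the immediate early genes have a median of 0.34 with LOC400043 siRNA 2.

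Other fixed lists held changed genes with LOC400043 silenced and were not shifted in camera. Since 3240 of all 18442 genes passed (1123 higher, 2117 lower), a few calls in a list do not set it apart. The shares of called genes in the small RNA pathway, interferon and microRNA lists below were smaller than that of all genes. Of 12 measured neighbours of LOC400043 on 12q13.13, 3 rose, over all genes and adjusted over the list alone, namely HOXC10 by 0.56 (SE 0.06), HOXC8 by 0.34 (SE 0.07) and CBX5 by 0.34 (SE 0.07), while 2 fell adjusted over the list alone (camera adjusted p = 0.534). HOXC10 measured 0.51 (SE 0.11, adjusted p = 0.119 in limma) with LINC00324 silenced, and the difference between both silencings was -0.05. In the small RNA pathway TNRC6A rose by 0.39 (SE 0.06) and SND1 fell by 0.54 (SE 0.06), the only changes among 16 genes by either adjustment (camera adjusted p = 0.834). Of 36 interferon response genes 3 rose, EIF2AK2 by 0.48 (SE 0.08), RIGI by 0.71 (SE 0.13) and IFI27 by 0.21 (SE 0.06), and IFI35 fell by 0.48 (SE 0.09), against 2 and 1 adjusted over the list alone (camera adjusted p = 0.377). Of 187 microRNA genes 4 rose and 4 fell, and 0 and 1 did when adjusted over the list alone (camera adjusted p = 0.234), with MIR218-1 at 0.50 (SE 0.08) and the miR-503 host gene MIR503HG at -0.45 (SE 0.06). Of 16 reported miR-96-5p targets 3 fell by either adjustment, RECK by 0.46 (SE 0.08) among them (camera adjusted p = 0.75). Of 29 replication-dependent histone genes 2 rose and 5 fell by either adjustment, and H1-3 fell by 0.67 (SE 0.09) (camera adjusted p = 0.405).

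The siRNAs against LOC400043 differed strongly from each other. With siRNA 2, ANXA1, the gene of annexin A1, rose by 3.16 (SE 0.08), to 8.94 times scramble, and EGR1, KRTAP21-2, ETV5 and TFPI rose by 2.13 to 2.31, while ACTA2 fell by 2.42 (SE 0.07), ERAL1, a chaperone of the mitochondrial ribosome, fell by 2.04 (SE 0.08) and NDUFV1 fell by 1.73 (SE 0.08). With siRNA 1, SYT11 rose by 2.02 (SE 0.09) and the bicarbonate transporter gene SLC4A8 by 1.62 (SE 0.07), and FLNA fell by 2.02 (SE 0.08) and OSTN fell by 1.92 (SE 0.12), as did the calponin gene CNN2 (-1.55, SE 0.07), DDX23 (-1.55, SE 0.09) and AP1B1 (-1.53, SE 0.07). Tested directly, siRNA 1 minus siRNA 2, the gap was -3.52 (SE 0.08) for ANXA1, 2.33 (SE 0.07) for ACTA2, 2.29 (SE 0.08) for ERAL1 and -2.30 (SE 0.16) for EGR1. SLC4A8, SYT11 and BEX1 were higher with siRNA 1 by 1.70 to 1.78, and KRTAP21-2, ETV5 and TFPI differed by -2.86 to -2.02. In limma, siRNA 1 changed 2125 genes (749 higher, 1376 lower), siRNA 2 changed 4013 (1458 higher, 2555 lower), and 3163 differed between them, 1780 higher and 1383 lower with siRNA 1. After median centring siRNA 2 gave 2187 higher and 1901 lower genes and the direct comparison gave 1388 higher and 1671 lower. Without replicate 1 or replicate 2 of siRNA 1 the count of siRNA 1 was 411 or 256, and the direct comparison gave between 987 and 1303 without any 1 of the 4 silenced arrays.

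Lists moved apart between the LOC400043 siRNAs as well. Of the 24 p53 targets 19 were higher with siRNA 1 than with siRNA 2, by a median of 0.55 (camera adjusted p = 1.04e-13, and adjusted p = 0.0947 with an estimated correlation). Of the 29 ATF4 response genes 18 were lower with siRNA 1, by a median of -0.38 (camera adjusted p = 9.42e-12, and adjusted p = 0.341 with an estimated correlation). DDIT3, a stress-induced transcription factor, measured -0.29 with siRNA 1 and rose by 1.48 with siRNA 2. Of the 20 immediate early genes 13 were lower and 1 higher with siRNA 1, by a median of -0.39 (camera adjusted p = 1.37e-10, and adjusted p = 0.375 with an estimated correlation), and JUN fell by 1.41 with siRNA 1 and rose by 0.58 with siRNA 2. Both siRNAs changed 1126 genes in the same direction, 354 higher and 772 lower, where independent lists would share 59.2 and 191, and 123 genes, BEX1 and JUN among them, in opposite directions. Of the 3240 genes called on the mean, 1242, ETV1 and FLNA among them, differed between the siRNAs. Over 18442 genes the effects correlated at 0.480 with a covariance of 0.0301, against 0.5 and 0.00454 for simulated unchanged groups, an excess covariance of 0.0256. With a different scramble array for each siRNA the correlation was 0.341 or 0.257.

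The last comparison set the cells with LINC00324 silenced against those with LOC400043 silenced, each relative to the scramble mean of its own table, because the tables were normalized separately. NQO1, an antioxidant enzyme gene, was higher with LINC00324 silenced by 1.16 (SE 0.06), the glutathione transferase gene GSTA4 by 1.12 (SE 0.06), ERAL1 by 1.09 (SE 0.05), LPCAT3 by 1.07 (SE 0.06) and BLMH by 1.07 (SE 0.05). Lower with LINC00324 silenced were ANXA1 (-1.68, SE 0.09), the kinase gene UHMK1 (-1.67, SE 0.04), EGR1 (-1.66, SE 0.06), SYT11 (-1.48, SE 0.08) and OR2B6 (-1.46, SE 0.11). NQO1, LPCAT3, BLMH, UHMK1 and OR2B6 had opposite signs with both silencings in all 8 arrays; UHMK1 lay at -0.87 to -0.49 with LINC00324 silenced and at 0.87 to 1.08 with LOC400043 silenced. For ANXA1 and ERAL1 siRNA 2 against LOC400043 alone made the difference: in the arrays of siRNA 1, ANXA1 lay at -0.32 and -0.40 and ERAL1 at 0.27 and 0.23, close to their means of -0.28 and 0.20 with LINC00324 silenced. EGR1 and LPCAT3 also differed mostly through siRNA 2 (2.25 and 2.38, against 0.13 and -0.09 with siRNA 1, for EGR1), and SYT11 mostly through siRNA 1 (1.94 and 2.10, against 0.27 and 0.35 with siRNA 2). The SEs come from replicates of an siRNA and leave out error in the offset between the tables, which the arrays of a silencing share. The 2 scramble arrays disagreed about this offset with an SD of 0.085 over genes on the log2 scale. In limma the 10 genes named above had adjusted p of 1.3e-05 to 0.000383. Of 18191 genes 3952 differed, 23 of them at least 2-fold. The split was 2104 higher and 1848 lower with LINC00324 silenced (2149 and 2184 after median centring). The count was 974 with each silencing as 1 group and 360 in a test against a fold of 1.2, and between 2205 and 2457 without any 1 array of LINC00324 siRNA 2 or of either LOC400043 siRNA.

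Silencing of either RNA also changed some genes in the same direction. Of the 36 genes that rose with LINC00324 silenced, 28 also rose with LOC400043 silenced, RNF167, NDUFB5, HIPK3 and SHMT2 among them, where independent lists would share 2.19, and 2 fell. Of 51 genes that fell with LINC00324 silenced and were measured in both, 32 also fell with LOC400043 silenced, where independent lists would share 5.84, and 2 rose. RNF167 rose with each of the 4 siRNAs, by 1.11, 1.34, 1.30 and 1.19, and NDUFB5 by 1.09, 1.21, 1.37 and 1.16. The effects of both silencings correlated at 0.479 over 18191 genes with a covariance of 0.017, against 0.644 and 0.00544 in simulated unchanged groups, an excess covariance of 0.0116. All 4 siRNAs share the same 2 scramble arrays. With a different scramble array for each silencing the correlation was 0.252 or 0.169, with a covariance of 0.0104 or 0.00787. The shared genes were not counted in this way, and part of their excess may come from the scramble arrays.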

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

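Quantile normalization and leaving out arrays were planned, but their use to weigh an explanation, and every other test in this part, was chosen after the results were seen; 3 patterns are weighed. No group holds enough arrays to test for a sample far from the others.

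The first pattern was a set of genes that moved alike with LINC00324 and with LOC400043 silenced against the same 2 scramble arrays, 28 that rose, all with the same sign with all 4 siRNAs, and 32 that fell on the mean of the siRNAs, of which 24 had the same sign with all 4. The other 8 lay above scramble with 1 LOC400043 siRNA, 7 of them with siRNA 1, FAS (0.036), EDA2R (0.017) and ZMAT3 (0.43) among them. Each differed among the 4 siRNAs in a test of any difference, so effects not alike for all siRNAs take part in these 8. They were picked because 1 siRNA lay above scramble, which makes such a difference likely beforehand. It is therefore no separate test of the scramble arrays or of a response common to all siRNAs. The size of the change differed among the 4 siRNAs for 67.9% of the genes that rose (19) and 84.4% of those that fell (27). This test of any difference does not tell a difference between the 2 RNAs from one between siRNAs against the same RNA. For these genes it shows effects not alike for all siRNAs but does not exclude a common shift beneath them. The share was 31.3% of all genes, which is no fair comparison because the shared genes were picked by their calls in the same arrays. For 9 genes that rose, RNF167 and NDUFB5 among them, and 5 that fell, TNFRSF10D and NOTCH1 among them, no difference was found. With no second kind of control, the scramble siRNA and a common response to silencing cannot be told apart for the 28 that rose or the 32 that fell.

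The second pattern was the difference between siRNAs against 1 RNA, with 571 genes for LINC00324 and 3163 for LOC400043 in limma. The LOC400043 count was 3381 after quantile normalization, which argues against remaining differences in distribution between arrays as the whole cause. The values were already normalized, and a second normalization cannot undo the first, so this decides nothing on the authors' normalization. Genes still differed past the threshold with any 1 array left out, which argues against 1 array as the whole cause. The LINC00324 count was 0 in limma without either siRNA 2 array (1755 and 1658 genes at an unadjusted p under 0.05) and 87 without either scramble array. Calls lost with 1 array left in a group do not show that array to be the cause, and the LINC00324 counts decide nothing on this explanation. LINC00324 RNA itself differed by -0.22 between its siRNAs (SE 0.15, 95% interval -0.59 to 0.15), which leaves unequal silencing open. Effects of an siRNA on RNAs other than its target may also contribute, and were not tested because siRNA sequences were not used here.

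The third pattern was lower RNA of p53 targets. Their median difference between siRNA 1 and siRNA 2 was 0.55 for LOC400043, with 19 of 24 higher with siRNA 1, and -0.17 for LINC00324. If the shared scramble arrays were the whole cause, the list would be lower with LOC400043 siRNA 1 as well, where its median was 0.07. This value and those 19 genes argue against it unless siRNA 1 raised the list by a like amount. After quantile normalization the median with LINC00324 silenced was -0.42, so the fall does not rest on remaining differences in distribution between arrays. The values were already normalized, so this decides nothing on the authors' normalization. A lower p53 response through the silenced RNAs may contribute to the LINC00324 result, where both siRNAs lowered the list. The fall of LINC00324 RNA was itself not past the threshold (adjusted p = 0.185 in limma). As p53 activity was not measured either, an effect of single siRNAs stays open.

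Between LINC00324 and LOC400043 silencing 3952 genes differed. With each silencing as 1 group the count was 974, and 1 of the 35 splits of the 8 silenced arrays into equal groups, the real one, gave as many. The 32 splits that part the replicates of an siRNA are no fair comparison. The real split alone also parts the 2 tables fully, so error in the offset between them may add to its count. Only 3 splits keep the replicates together, too few for a share under 0.05. The highest other of these, siRNA 1 against siRNA 2 of both RNAs, gave 105. The genes named for this difference were NQO1 (1.16), GSTA4 (1.12), ERAL1 (1.09), LPCAT3 (1.07), BLMH (1.07), ANXA1 (-1.68), UHMK1 (-1.67), EGR1 (-1.66), SYT11 (-1.48) and OR2B6 (-1.46), on the log2 scale.

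In a direct test of siRNA 1 minus siRNA 2, camera passed 10 of 30 lists for LINC00324 and 12 of 30 for LOC400043, and with an estimated correlation none passed (smallest adjusted p = 0.0947). Among lists shifted against scramble on the mean, or in opposite directions by each siRNA, these were, besides the p53 targets, the ATF4 response with a median of -0.12 for LINC00324 and -0.38 for LOC400043, and for LOC400043 the immediate early genes (-0.39) and the ribosomal proteins (-0.084). With an estimated correlation their adjusted p was 0.845, 0.341, 0.375 and 0.375. Of the other lists, the box H/ACA snoRNAs had the smallest p, with a median of -0.18 for LINC00324 (adjusted p = 1.81e-09) and -0.17 for LOC400043 (adjusted p = 2.86e-07). The genes named for LINC00324 that differed in the same way were LOC388022 (1.64), ANXA3 (1.34), PRKCH (1.25), PAFAH1B2 (1.23), EDIL3 (1.23), ETV1 (0.91), SPATA18 (-0.55), TPI1 (-1.24), ZPR1 (-1.24), HDHD5 (-1.26), MRPL51 (-1.30) and ADCY10P1 (-2.05). Those higher with LOC400043 siRNA 1 were ACTA2 (2.33), ERAL1 (2.29), SLC4A8 (1.78), SYT11 (1.71), BEX1 (1.70), NUDT11 (1.36), RUNX1T1 (1.32), HFM1 (1.26), ISYNA1 (0.77), LMF1 (0.75), MOCOS (0.47) and FAH (0.33). Those lower with it were ANXA1 (-3.52), KRTAP21-2 (-2.86), EGR1 (-2.30), ETV5 (-2.12), TFPI (-2.02), FLNA (-1.66), SEMA3C (-1.55), ETV1 (-1.36), GRIK1-AS2 (-1.25), SLC10A5 (-1.20), HIPK3 (-0.81) and RRH (-0.80).

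The 10355 features with no name in either table, which the comparisons of genes leave out, also held signals in limma. LINC00324 siRNA 1 changed 1 of them, siRNA 2 changed 30, and 34 differed between these siRNAs, while the mean of both siRNAs gave 0 (810 at an unadjusted p under 0.05). Between the LOC400043 siRNAs 534 differed, 260 higher and 274 lower with siRNA 1.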

How the results depend on the processing

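The fit of all 10 arrays joined through the scramble arrays and the crossed replicate numbering were chosen after the data were seen. No named gene, list or correlation past its threshold reversed its sign under the alternatives run, but the excess of higher or lower genes turned in some counts. It turned with median centring for LOC400043 siRNA 2 (2187 higher and 1901 lower), for the direct comparison of the LOC400043 siRNAs (1388 and 1671), for LINC00324 silencing (35 and 34) and for LINC00324 against LOC400043 (2149 and 2184). For LINC00324 silencing it also turned after quantile normalization (156 and 152), over all features (14 and 9), with the siRNAs as 1 group (13 and 6), against a fold of 1.2 (9 and 3), with each siRNA passing (17 and 16) and without siRNA 1 replicate 1 (49 and 48). LINC00324 siRNA 1 turned after quantile normalization (179 and 161), with array weights (23 and 21) and without its replicate 1 (44 and 23), and LINC00324 against LOC400043 turned without LINC00324 siRNA 1 replicate 2 (2644 and 2805). The cause of each change below was not tested unless it is given.

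The number of genes called with LINC00324 silenced changed under many alternatives. For the mean of the siRNAs (88), siRNA 1 (92), siRNA 2 (337) and siRNA 1 against siRNA 2 (571), a filter on dim genes gave 904, 719, 1311 and 1564, a trended and robust variance 1060, 921, 1491 and 1856, and quantile normalization 308, 340, 779 and 1152. All 10 arrays joined gave 849, 706, 1399 and 1683, and all features of the value table, which tests more features, gave 23, 30, 187 and 263. Array weights gave 44 for siRNA 1 and 1130 for siRNA 2. The mean gave 19 with the siRNAs as 1 group, 12 in the test against a fold of 1.2 and 33 where each siRNA alone had to pass, which are stricter by construction or add the siRNA difference to the spread. The filter on dim genes leaves out LINC00324 itself.

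With LOC400043 silenced (3240) the count was 599 with the siRNAs as 1 group, 357 against a fold of 1.2 and 1126 where each siRNA had to pass, and siRNA 1 (2125) gave 3207 with the filter on dim genes and 3464 with the trended and robust variance. LINC00324 against LOC400043 (3952) gave 974, 360 and 1480 with 1 group per RNA, against a fold of 1.2 and with each siRNA passing. Of the lists, 6 were shifted with LINC00324 silenced and 4 with LOC400043 silenced in camera, 0 and 0 with an estimated correlation, and 3 and 3 in fry. With scramble arrays not shared between siRNAs, the correlation of effects was 0.196 or 0.116 for LINC00324 and 0.341 or 0.257 for LOC400043, which shows that shared arrays raise it.

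The differences between replicates correlated across genes at 0.60 between scramble and LINC00324 siRNA 1. With LINC00324 siRNA 2 they correlated at -0.19 for scramble and -0.38 for siRNA 1, and in the LOC400043 table at 0.23, 0.37 and 0.09. The replicate numbers thus did not pair all groups alike. A component shared between groups is not excluded, and the main fit has no term for one. With the replicate number as a block the counts were 71, 82, 301 and 467 for LINC00324, 4008, 2820, 4810 and 3771 for LOC400043 and 3667 between them. Crossing the numbers of LINC00324 siRNA 2 in the block gave 565, 460, 1153 and 1469 for LINC00324.

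Each array was left out in turn, and a lone array was then assumed to vary like the other groups. The mean of the LINC00324 siRNAs ranged from 0 to 161, siRNA 1 from 0 to 70, siRNA 2 from 0 to 745 and siRNA 1 against siRNA 2 from 0 to 622 in limma. The first 3 counts were 0 without scramble replicate 1 (2035, 2087 and 2257 genes at an unadjusted p under 0.05), scramble replicate 2 (1417, 1409 and 1965), siRNA 2 replicate 1 (1657, 1631 and 1736) and siRNA 2 replicate 2 (1382, 1631 and 1326). The direct comparison was 0 without siRNA 2 replicate 1 or 2 (1755 and 1658), 87 without either scramble array and 344 without siRNA 1 replicate 2. The mean gave 161 without siRNA 1 replicate 2, and siRNA 2 gave 745 without either siRNA 1 array. Of the 27 named genes called on the mean, 27 stayed past the threshold after quantile normalization, 23 after median centring and 15 over all features of the value table. The LINC00324 level ranged from -0.57 to -0.40, the correlation of effects from 0.253 to 0.592, and the lists shifted from 5 to 11.

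The LOC400043 mean ranged from 1462 to 3154, with 1703, 1462, 1798 and 1846 without siRNA 1 replicate 1, siRNA 1 replicate 2, siRNA 2 replicate 1 and siRNA 2 replicate 2. In the same order siRNA 1 gave 411, 256, 1316 and 1316 (256 to 2316 over all arrays), and the direct comparison gave 987, 1156, 1275 and 1303 (987 to 3686). LOC400043 siRNA 2 gave 1785 and 1864 without its replicate 1 and 2 (1785 to 3917). The correlation ranged from 0.442 to 0.574 and the lists from 2 to 5. LINC00324 against LOC400043 ranged from 2205 to 5449, with 2205 to 2457 without any 1 array of LINC00324 siRNA 2 or of the LOC400043 siRNAs. The level of LOC400043, and all features of the value table for LOC400043 against scramble or LINC00324, were not run.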

Other observations

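Both tests in this part were chosen after the results were seen. Their p-values are unadjusted, while those of the fixed lists were adjusted over the lists. Unadjusted, the p53 targets had camera p = 0.0148 with LINC00324 silenced and p = 0.0114 with LOC400043 silenced, with an estimated correlation. With LOC400043 siRNA 2, ETV5 rose by 2.26 and EGR1 by 2.31 against scramble, and a candidate explanation is stronger output of the MAPK pathway, which induces both. In a list of 13 genes that read this pathway, 5 were higher with siRNA 2 than scramble, SPRED2 by 1.32, SPRY2 by 0.81, SPRED1 by 0.61, ETV4 by 0.59 and SPRY4 by 0.48. The median of the list was 0.28 (camera p = 4.59e-05, and p = 0.031 with an estimated correlation). The 9 genes outside the fixed lists had a median difference of -0.32, siRNA 1 minus siRNA 2 (camera p = 0.000316, and p = 0.0333 with an estimated correlation). These values are in line with the hypothesis for siRNA 2. The median of the list was 0.10 with siRNA 1, and the direct difference between the siRNAs leaves open whether the pattern follows from loss of LOC400043 or from siRNA 2 itself. The list also differed between the LINC00324 siRNAs, by a median of 0.15 (13 genes, camera p = 0.000402, and p = 0.0406 with an estimated correlation), so a difference of this list is not specific to LOC400043 siRNA 2. Pathway activity was not measured.

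FLNA, CNN2 and ACTA2, which encode parts of the actin cytoskeleton, were lower with LOC400043 silenced, and a lower programme of the transcription factor SRF was tested as an explanation. The median of the other genes of an SRF and actin list was 0.030 (camera p = 0.651, and p = 0.66 with an estimated correlation), with 2 higher and 1 lower. CNN2 fell with siRNA 1 only and FLNA fell more with siRNA 1, where the list had a median of -0.041 and ZYX fell by 0.36, and ACTA2 fell with siRNA 2, where the list had a median of 0.10, ANKRD1 rose by 1.59 and ACTN1 fell by 0.51. The list differed between the siRNAs by a median of -0.11 (camera p = 0.00409, and p = 0.0536 with an estimated correlation). Members that went both ways decide nothing, and the explanation stays open.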
